A study of Arabidopsis thaliana with 18 samples.

How the data were processed

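Messenger RNA of Arabidopsis thaliana roots was measured on Affymetrix ATH1 arrays, which read each transcript with a set of short probes. The 18 arrays fall into 6 groups of 3, made of 3 genotypes, each with and without the root-colonizing bacterium Pseudomonas WCS417. The genotypes were the wild type Col-0, the mutant myb72-2, and oxMYB72, a line that carries a tagged MYB72 under a constitutive viral promoter in the myb72-2 background. Groups and replicate numbers were taken from the sample titles. Nothing in the labels used here says how many separate plant batches the replicates come from, so p-values measure the spread between these samples, which may in part be technical.

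The deposited values are expression values that the authors made with RMA (background correction, quantile normalization and summary of the probes of a set), per the submitters' processing notes. The RMA version is not given in the sources used here. That the deposited values are on the log2 scale was taken from RMA, which gives such values, and from their range of 2.42 to 14.63. The array medians lay between 6.291 and 6.414 and the interquartile ranges between 3.913 and 4.2, so the distributions were alike but not identical. RMA makes the arrays alike in distribution, so a change shared by most genes would not be seen, and it compresses large differences near the background. The number of arrays limits the precision.

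Of 22810 probe sets, 64 control probe sets were left out, and 22746 were tested. Gene names came from the platform annotation given, with symbols updated through the gene identifier in a RefSeq gene table of the assembly TAIR10.1, which was used only for names and for the order of neighbouring genes. Exactly 1 gene was named for 13513 probe sets (59.4%), several for 503, and none in the annotation used for 8730, which are therefore unnamed here and not without a gene. Of the named ones 13436 matched a locus. No probe set was named MYB72 in that annotation, so the level of the mutated gene is not reported and the genotype labels could not be checked against it.

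All 13 comparisons came from one limma model (version 3.58.1, R 4.3.3) with a mean per group over all 18 arrays, moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets within a comparison. A probe set was called at an adjusted p under 0.05. Fold changes are differences of mean log2 values, and errors printed after ± are standard errors from that model unless given as SD. On simulated arrays with the spread of the real ones and 22746 probe sets, the WCS417 effect in Col-0 was recovered for 52.2% of 67 probe sets changed by 0.5 on the log2 scale and 100% of 67 changed by 1. For the difference of the WCS417 effect between oxMYB72 and Col-0 the shares, again of 67 changed probe sets each, were 6% and 91%.

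Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over all lists tested within a comparison, on 1 probe set per gene (the brightest), over 13355 genes. The lists written before the data were examined numbered 30, with 388 entries. Only 48 of these entries were measured by a probe set of a single named gene. A further 22 lists of gene families and processes were added from the annotation, after it had been read and before any test was run. Lists with fewer than 3 measured members were not tested as lists, which left 25 tested lists. A list entry counted where the gene table gave its symbol for that locus or gave the locus no symbol. Otherwise the symbol's own locus was used if it was unique, and the entry was left out if not.

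Named genes followed a rule fixed before the data were examined: probe sets of a single gene that were called and whose groups did not overlap in any array, the 8 largest rises and 8 largest falls per comparison (5 and 5 for oxMYB72 against Col-0 and for differences of effects, the latter with no condition on overlap), BGLU42, and up to 3 called members per list. For 3 arrays against 3, groups do not overlap by chance in 10% of splits. Alternatives were quantile normalization again, median centring, a variance trend with robust moderation, only the arrays compared, removal of the 30% dimmest probe sets, a replicate block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.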

Results

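Roots of 19-day-old seedlings were profiled in 6 groups of 3 arrays: Col-0, myb72-2 and oxMYB72, each without bacteria and 2 days after inoculation with WCS417, a beneficial rhizobacterium that colonizes roots and primes systemic resistance. MYB72 is a transcription factor of roots. No probe set bore its name in the annotation used, so its level is not given. Replicate arrays of a group correlated between 0.9913 and 0.9977 across probe sets. The difference between 3′ and 5′ probe sets of actin, a sign of RNA quality, lay between 1.1 and 1.48 on the log2 scale over the 18 arrays. It was larger with WCS417 by a mean of 0.1 over the genotypes (exact permutation within genotypes, two-sided, p = 0.0322, 0.0483 adjusted over 3 transcripts). That of GAPDH was larger by 0.11 (exact p = 0.00875, adjusted 0.0262), and that of ubiquitin differed by -0.05 (exact p = 0.264, adjusted 0.264).

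The largest rises in Col-0 were in AT1G26380 (6.77 ± 0.55 on the log2 scale, 109-fold) and its neighbours AT1G26390 (6.45 ± 0.37) and AT1G26410 (4.69 ± 0.26), members of the berberine bridge enzyme-like family. AT3G12900, which encodes the scopoletin 8-hydroxylase of coumarin synthesis, rose by 5.4 ± 0.21, from 5.17 ± 0.47 to 10.58 ± 0.14 (SD, n = 3). AT3G24510 (5.3), AT5G38910 (4.82), AT3G60270 (4.43) and AT4G37290 (4.19) complete the 8 largest rises. The largest falls were in HIS1-3, a linker histone (-3.57 ± 0.33), CCL (-2.5), AT1G62510 (-2.41), AT2G22510 (-2.01), AT2G15960 (-2), AT1G64590 (-1.95), AT3G19430 (-1.83) and MGL, a methionine gamma-lyase (-1.83). In limma, 3491 probe sets were called, 1452 higher and 2039 lower, and 2290 were called without Col-0 control replicate 3. Between these groups the 3′ minus 5′ difference was larger with WCS417 by 0.09 for actin and 0.15 for GAPDH.

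Genes of coumarin synthesis and export rose as a list in Col-0 (camera adjusted p = 4.84e-08, adjusted p = 0.00297 with an estimated correlation). Adjusted over the list alone, 6 of 7 measured members were called, counted in either direction. Over all probe sets none was called lower and 5 were called higher. Beside AT3G12900 they included BGLU42, a beta-glucosidase (2.17 ± 0.12), and AT3G13610, a feruloyl-CoA hydroxylase (2.02 ± 0.12). Of the iron uptake list 2 genes were measured, and both rose, also when adjusted over the list alone: AT3G58060, a manganese transporter, by 3.08 ± 0.15 and CYP71B5, a cytochrome P450, by 2.19 ± 0.16. In the iron deficiency signalling list 3 of 10 members were higher and 2 lower, 8 were called when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0928). AT1G47400, an iron-responsive small peptide, rose by 1.83 ± 0.25. The immune regulator WRKY53 rose by 1.46 ± 0.14, the zinc transporter ZIP9 by 1.41 ± 0.17, and the sugar transporter SWEET2 fell by 0.80. Nuclear photosynthesis genes, a list added later and a marker of green tissue, fell in 13 of 20 members (camera adjusted p = 2.81e-11; adjusted p = 0.0194 with an estimated correlation), among them NdhS (-1.34), LHCB4.2 (-1.14) and LHCB4.1 (-1.1). Plastid-encoded genes were lower in 9 of 69 members, 7 when adjusted over the list alone (camera adjusted p = 3.77e-05, adjusted p = 0.367 with an estimated correlation). This list also holds genes not of photosynthesis, such as clpP and rpl14, so it does not mark green tissue alone.

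**Figure D1:**
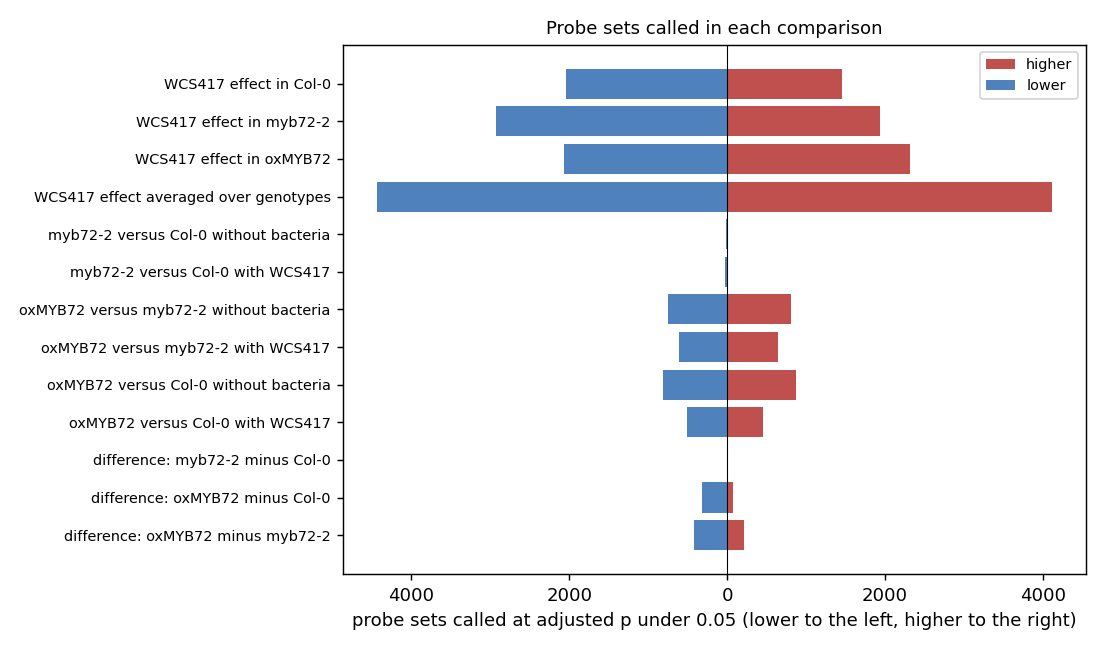
Number of probe sets called at an adjusted p under 0.05 (horizontal axis) in each of the 13 comparisons, higher to the right and lower to the left. The WCS417 effects call between 3491 and 8549 probe sets, and the comparisons of myb72-2 with Col-0 call 9 and 29.

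In myb72-2 the response to WCS417 was led by many genes that also led it in Col-0. AT1G26380 (6.1 ± 0.55), AT1G26390 (5.89 ± 0.37), AT3G12900 (5.09 ± 0.21), AT3G24510 (5.09 ± 0.18), AT5G38910 (4.97), AT1G26410 (4.75), AT5G39580, a peroxidase (4.67), and AT3G60270 (4.37) rose most in myb72-2. The untreated mutant arrays were far apart in AT1G26380 (4.83 ± 1.85) and AT1G26390 (4.36 ± 1.16; SD, n = 3), and without myb72-2 control replicate 2 the rises were 7.16 and 6.56. HIS1-3 (-4.15), MGL (-2.46), CCL (-2.46), AT1G62510 (-2.39), AT2G22510 (-2.36), AT1G05340 (-2.08), AT2G15960 (-1.94) and AT4G38080 (-1.84) fell most. Coumarin genes rose in 5 of 7 members, 5 also when adjusted over the list alone (camera adjusted p = 6.47e-05; adjusted p = 0.0201 with an estimated correlation), and nuclear photosynthesis genes fell in 15 of 20 (camera adjusted p = 3.67e-11; adjusted p = 0.0201 with an estimated correlation). Xyloglucan endotransglucosylases, a list added later of enzymes that remodel cell walls, were higher in 5 and lower in 2 of 9 members (camera adjusted p = 0.0173; adjusted p = 0.312 with an estimated correlation and 0.057 without the dimmest genes), led by XTH26 (2.5 ± 0.19). Immune signalling genes, another list added later, were higher in 8 and lower in 2 of 20 (camera adjusted p = 0.0177; adjusted p = 0.312 with an estimated correlation and 0.065 without myb72-2 control replicate 1). The call covered 4870 probe sets, 1938 higher and 2932 lower. The 3′ minus 5′ difference was larger with WCS417 by 0.07 for actin and 0.03 for GAPDH. Across the 22746 probe sets the effects in Col-0 and myb72-2 correlated at 0.892 (genes are not independent replicates), and 1105 probe sets were higher in both against 123.7 for independent lists, with 1677 lower in both against 262.8.

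In oxMYB72, ATPMEPCRB, a pectin methylesterase (4.13 ± 0.17), AT3G58060 (3.89 ± 0.15), AT3G12900 (3.68 ± 0.21), AT2G43620, a chitinase family protein (3.66), AT5G39580 (3.43), AT5G64120, a peroxidase (3.2), AT3G61930 (3.06) and AT2G25150 (2.87) rose most, and BGLU42 rose by 2.35. HIS1-3 (-3.92), AT1G62510 (-2.4), AT2G22510 (-2.35), SUFE2 (-2.13), AT5G14730 (-1.96), AT4G38080 (-1.93), AT1G51830 (-1.93) and MGL (-1.92) fell most. In the iron deficiency signalling list 6 of 10 members were higher and 1 lower, 7 also when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.125 with an estimated correlation), among them BHLH101, a regulator of the iron response (1.56). Coumarin genes were higher in 3 of 7 members and lower in 1, and 5 were called when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.125 with an estimated correlation). Expansins, a list added later of proteins that loosen cell walls, were higher in 7 of 18 (camera adjusted p = 0.000758; adjusted p = 0.125 with an estimated correlation), with EXPB2 at 1.89 ± 0.21, EXPA15 at 1.57 and EXPB3 at 1.52. Xyloglucan endotransglucosylases were higher in 5 and lower in 2 of 9 (camera adjusted p = 0.0123; adjusted p = 0.18 with an estimated correlation). Nuclear photosynthesis genes fell in 12 of 20 (camera adjusted p = 1.71e-06; adjusted p = 0.125 with an estimated correlation). In all, 4391 probe sets were called, 2324 higher and 2067 lower, whereas after median centring more were lower (2487) than higher (1886), a share higher of 43.1% against 52.9%. Without oxMYB72 control replicates 1 and 2, 1504 and 1548 were higher. The 3′ minus 5′ difference was larger with WCS417 by 0.15 for both actin and GAPDH. The effect correlated at 0.678 with that in Col-0 and at 0.651 with that in myb72-2 across probe sets.

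**Figure D2:**
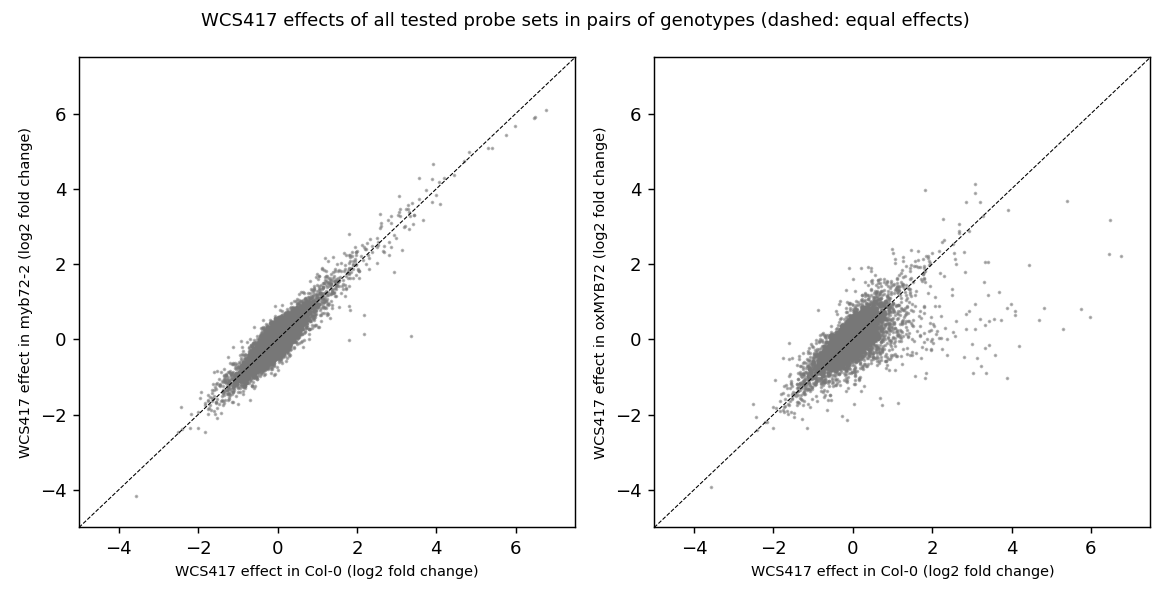
WCS417 effect (log2 fold change) of each tested probe set in Col-0 on the horizontal axis against myb72-2 (left) and oxMYB72 (right) on the vertical axis, with a dashed line of equal effects. The correlation across probe sets is 0.892 on the left and 0.678 on the right, where a group of probe sets induced in Col-0 lies near 0.

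Averaged over the genotypes, WCS417 raised AT1G26380 (5.03), AT1G26390 (4.87), AT3G12900 (4.72 ± 0.12), AT5G39580 (4.01 ± 0.1), AT3G60270 (3.6), ATPMEPCRB (3.53), AT3G58060 (3.42) and AT2G43620 (3.28) most. It lowered HIS1-3 (-3.88 ± 0.19), AT1G62510 (-2.4), AT2G22510 (-2.24), CCL (-2.23), MGL (-2.07), AT2G15960 (-1.91), AT4G38080 (-1.84) and AT5G54300 (-1.74) most. Coumarin genes were higher in 5 of 7 members and lower in 1, and 6 were called when adjusted over the list alone (camera adjusted p = 0.000442; adjusted p = 0.0285 with an estimated correlation). Nuclear photosynthesis genes fell in 15 of 20 and rose in 1 (camera adjusted p = 3.88e-10; adjusted p = 0.0285 with an estimated correlation). Plastid-encoded genes were lower in 17 of 69 and higher in 5, 22 also when adjusted over the list alone (camera adjusted p = 0.00776; adjusted p = 0.562 with an estimated correlation and 0.05 without myb72-2 WCS417 replicate 2). The average called 8549 probe sets, 4114 higher and 4435 lower, of which 445 changed at least 2-fold.

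Without bacteria, few genes stood apart between myb72-2 and Col-0. QQS, an orphan gene of carbon and nitrogen allocation, was lower in the mutant by -1.37 ± 0.13 on the log2 scale, AT5G35940 by -1.47 ± 0.22, AT1G43590 by -1.14 and AT3G01830 by -1.04. TPLATE (-0.56), AT3G01720 (-0.54) and MPPBETA (-0.52), which lie in a run of neighbouring genes on chromosome 3 that was lower in both lines than in Col-0, were lower too. AT3G03670, a peroxidase, was higher (1.01 ± 0.18, adjusted p = 0.047). Plastid-encoded genes were lower as a list, although limma called 0 of 69, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.0106; adjusted p = 0.756 with an estimated correlation). That list call ended without Col-0 control replicates 1 (0.15) or 3 (0.92) or myb72-2 control replicates 2 (0.46) or 3 (0.059). BGLU42 stood at 7.4 ± 0.11 in Col-0 and 7.36 ± 0.11 in myb72-2 (SD, n = 3). Only 9 probe sets were called, 1 higher and 8 lower. That count fell to 1 when limma was given only the arrays compared, to 1 without myb72-2 control replicate 1, to 4 without replicate 2 of that group, and to 2 and 3 without Col-0 control replicates 2 and 3. QQS kept its call without each of the arrays. AT3G03670 (0.79 to 1.16), TPLATE (-0.62 to -0.48) and MPPBETA (-0.55 to -0.47) lost theirs without any 1 of the 6 arrays, AT3G03670 also under median centring (1.02) and without the dimmest probe sets (1.01), and AT3G01720 (-0.57 to -0.47) without any but myb72-2 control replicate 3. AT5G35940 lost its call without Col-0 control replicate 2 (-1.46) or myb72-2 control replicate 1 (-1.36), AT1G43590 without Col-0 control replicate 3 (-1.04) or myb72-2 control replicate 1 (-1.16), and AT3G01830 without Col-0 control replicates 2 (-1.01) or 3 (-0.88) or myb72-2 control replicate 1 (-1). Under median centring 8 were called, 0% of them higher against 11.1% before.

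With WCS417, a few genes stood apart between mutant and wild type. CYP71B5 was lower in myb72-2 by -1.99 ± 0.16, AT5G55620 by -1.8 ± 0.17, and BGLU42 by -1.56 ± 0.12, followed by AT5G26270 (-1.02), QQS (-0.96), PR-1-LIKE (-0.86), AT1G70880 (-0.83) and AT5G23840 (-0.75). AT3G42910 was higher (0.57 ± 0.11). The iron deficiency signalling list was lower as a whole although limma called none of its 10 members over all probe sets, with 4 at an unadjusted p under 0.05, and 3 were called when adjusted over the list alone (camera adjusted p = 0.000226; adjusted p = 0.0346 with an estimated correlation). Coumarin genes were lower as a list (camera adjusted p = 0.00239, adjusted p = 0.0613 with an estimated correlation and 0.05 without myb72-2 WCS417 replicate 3). Of the 7 members 1, BGLU42, was called, and 3 when adjusted over the list alone, counted in either direction. Nuclear photosynthesis genes were lower as a list, with 2 of 20 called when adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.249 with an estimated correlation and 0.13 without myb72-2 WCS417 replicate 3). The call covered 29 probe sets, 4 higher and 25 lower. It ranged widely with single arrays: 11 without Col-0 WCS417 replicate 3, 12 without replicate 1 of that group, 47 without myb72-2 WCS417 replicate 1 and 121 without its replicate 3, of which 72 were higher and 49 lower, a share higher of 59.5% against 13.8%. The 4 higher ones became 11 and 2 without replicates 1 and 2 of that group and 1 without Col-0 WCS417 replicates 1 or 3. Another split of these 6 arrays, across genotypes, called 260. AT3G42910 lost its call without any of the 3 Col-0 arrays or myb72-2 replicates 1 or 2 (0.45 to 0.61), AT5G26270 without any of the Col-0 arrays or myb72-2 replicate 2 (-1.03 to -0.91), AT5G23840 without Col-0 replicates 1 (-0.67) or 3 (-0.72) or myb72-2 replicate 2 (-0.65), and PR-1-LIKE without Col-0 replicates 1 (-0.83) or 3 (-0.8). With only the arrays compared 6 probe sets were called, all lower, and of the named genes CYP71B5, AT5G55620 and BGLU42 kept their calls. Under a variance trend with robust moderation 45 were called.

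The test of the difference between the 2 responses called 4 probe sets, all with a smaller WCS417 effect in myb72-2. They were CYP71B5 (-2.03 ± 0.22), AT5G55620 (-1.8 ± 0.24), BGLU42 (-1.52 ± 0.17) and a probe set with no gene in the annotation used (-3.25 ± 0.26), which was chosen after its values were seen. CYP71B5 went from 3.34 ± 0.18 to 5.53 ± 0.27 in Col-0 and from 3.38 ± 0.1 to 3.54 ± 0.09 in myb72-2 (SD, n = 3). BGLU42 still rose in the mutant, to 8.02 ± 0.09, against 9.58 ± 0.17 in Col-0. The WCS417 effects in myb72-2 of CYP71B5 (0.15) and AT5G55620 (-0.01) were not called. In colonized oxMYB72 roots BGLU42 stood at 9.6 ± 0.24, CYP71B5 at 5.05 ± 0.4 and AT5G55620 at 5.28 ± 0.5. Coumarin genes had a smaller effect in myb72-2 as a list, with 1 of 7 called and 1 when adjusted over the list alone (camera adjusted p = 0.0084, adjusted p = 0.0912 with an estimated correlation). The called member was BGLU42, already counted among the 4 above, and the list was not tested without it. That list call ended without myb72-2 control replicate 2 (0.11) and myb72-2 WCS417 replicates 1 (0.068) or 3 (0.06). The iron deficiency signalling list also had a smaller effect, although limma called 0 of 10, with 3 at an unadjusted p under 0.05 and 1 called when adjusted over the list alone (camera adjusted p = 0.0084; adjusted p = 0.0912 with an estimated correlation and 0.11 without Col-0 WCS417 replicate 3). The count was 2 without the dimmest probe sets, and 17 of 100 regroupings of the arrays, which also respond to constant differences between genotypes, called at least 4, against 2 of 100 with genotype effects removed. Plastid-encoded genes had a less negative effect in myb72-2 as a list, although limma called 0 of 69, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0159; adjusted p = 0.604 with an estimated correlation). That call ended without Col-0 control replicates 1 (0.08) or 3 (0.44), Col-0 WCS417 replicate 2 (0.15), myb72-2 control replicate 2 (0.23) or myb72-2 WCS417 replicates 1 (0.068) or 3 (0.85).

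**Figure D3:**
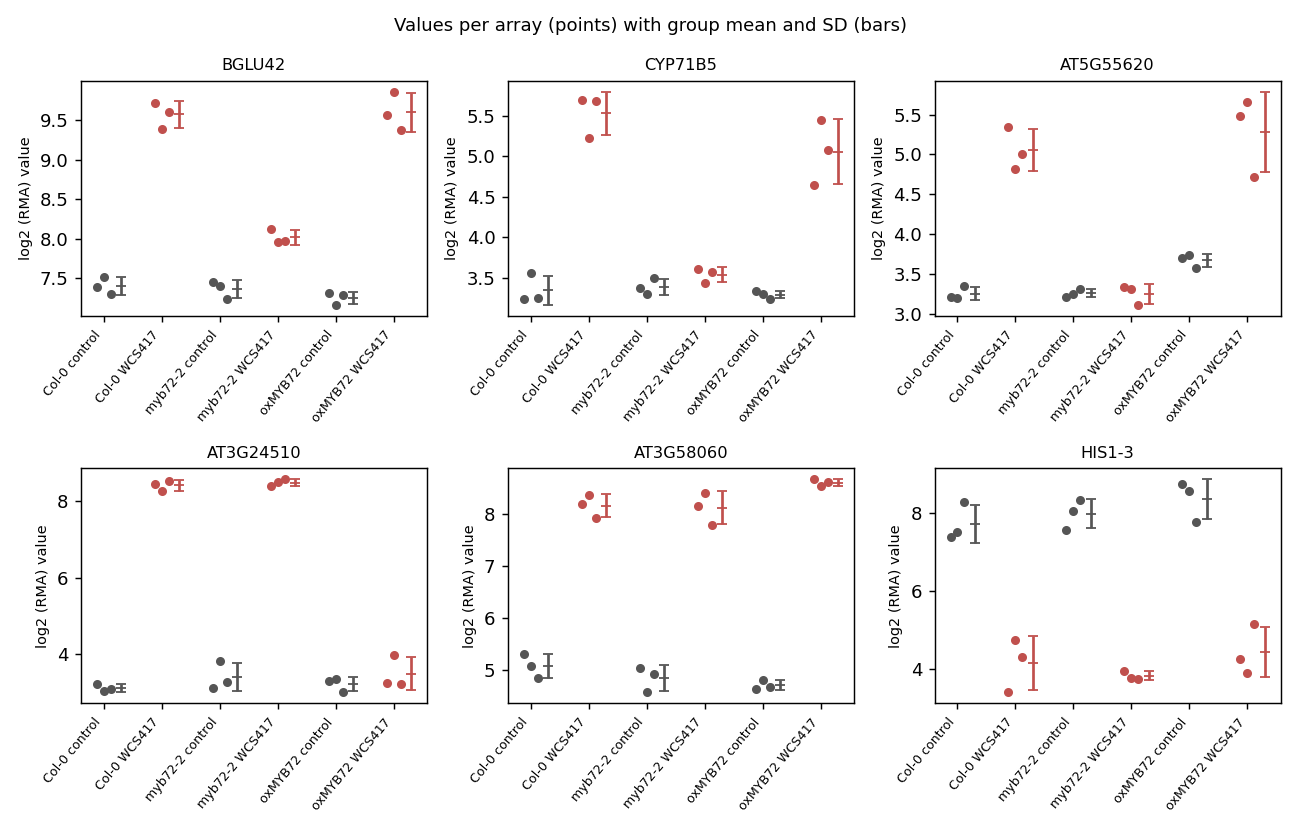
Log2 (RMA) values of 6 genes in each array (points, 3 per group) with the group mean and SD (bars), without bacteria in grey and with WCS417 in red. BGLU42 rises less in myb72-2 than in Col-0, and CYP71B5 and AT5G55620 rise in Col-0 with no called change in myb72-2. AT3G24510 stays near 3.49 in colonized oxMYB72, and AT3G58060 rises and HIS1-3 falls in each genotype.

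Of the 25 probe sets lower in colonized myb72-2 than in Col-0, 13 were higher in colonized oxMYB72 than in myb72-2 and 3 were lower still. Both comparisons use the myb72-2 WCS417 arrays, so part of this arises by chance: adjusted over the 25 alone, 14 were higher and called, against a mean of 6.1 and at most 13 in 100 simulations without effects. By sign alone 19 of 25 were higher, fewer than the mean of 24.1 in those simulations. Against colonized Col-0, whose arrays also served to choose the 25, 11 were still called lower in oxMYB72 and 11 were not called. The 25 include 4 genes of the chromosome 3 run described below.

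Untreated oxMYB72 roots differed widely from their myb72-2 background. AT4G33720, a pathogenesis-related protein, was higher by 7.69 ± 0.36, at 13.14 ± 0.06 against 5.45 ± 1.14 (SD, n = 3), and by 8.34 without myb72-2 control replicate 1. AT5G42830, an acyltransferase (3.59 ± 0.15), AT1G26420 (2.95), AT1G12130 (2.85), AT1G75290 (2.5), HCT, an enzyme of phenylpropanoid synthesis (2.34 ± 0.11), AT5G61290 (2.26) and AT4G33666 (2.24) followed. AT4G12500 (-2.81 ± 0.2), AT1G02305 (-2.73), AT5G37450 (-2.63), AT1G52820 (-1.9), AT4G07820 (-1.62), AT5G14650 (-1.58), AT5G41280 (-1.41) and UGT72E1 (-1.39) were lower. Coumarin genes were higher in 4 of 7 members, 4 also when adjusted over the list alone (camera adjusted p = 1.35e-06; adjusted p = 0.00595 with an estimated correlation), with AT3G12900 at 1.54, AT3G13610 at 1.45 and AT1G28680 at 1. BGLU42 differed by -0.11 and was not called. Nuclear photosynthesis genes were lower in 5 of 20 (camera adjusted p = 0.00222; adjusted p = 0.333 with an estimated correlation and 0.052 without oxMYB72 control replicate 3). In all 1548 probe sets were called, 804 higher and 744 lower, and 1005 without oxMYB72 control replicate 2. The lower ones numbered 412, 483 and 492 without myb72-2 control replicates 1, 2 and 3, and 465 and 424 without oxMYB72 control replicates 1 and 2. The share higher was 51.9%, but 67.4% after median centring and 47.4% with only the arrays compared.

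With WCS417, oxMYB72 exceeded myb72-2 in AT4G33720 (4.82 ± 0.36), AT4G33710 (2.15), AT5G55620 (2.03), AT5G61290 (1.92), AT1G12130 (1.76), EXPB2 (1.72), HCT (1.7) and AT4G22610 (1.68), and BGLU42 was higher by 1.58. It lay far below in AT3G24510 (-5.01 ± 0.18), AT4G37290 (-4.48), AT1G26380 (-4.37), AT1G26410 (-4), AT2G23270 (-3.8), AT5G22555 (-3.61), AT1G26390 (-3.47) and AT4G12500 (-3.25). The iron deficiency signalling list was higher, with 3 of 10 members called and 4 when adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.0337 with an estimated correlation), and the immune signalling list added later was lower, with 5 of 20 called (camera adjusted p = 0.00231; adjusted p = 0.193 with an estimated correlation), among them CML37 (-0.99), STZ (-0.88) and CML42 (-0.85). Coumarin genes were called as a list in camera too, in a direction not given here. That list call ended without myb72-2 WCS417 replicates 1 (camera adjusted p = 0.18) or 3 (0.088) or oxMYB72 WCS417 replicates 1 (0.061) or 3 (0.058). The call covered 1256 probe sets, 651 higher and 605 lower, and 588 with only the arrays compared. The share higher was 51.8%, but 49.7% after median centring, 48.6% after quantile normalization again and 45.2% with only the arrays compared. Without oxMYB72 WCS417 replicate 3, AT4G33710 was higher by 2.82.

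Against Col-0, untreated oxMYB72 was higher in AT4G33720 (9.06 ± 0.36), AT5G42830 (3.69), AT1G12130 (2.94), AT1G26420 (2.91) and AT1G75290 (2.49) and lower in AT4G12500 (-3.34), AT1G02305 (-2.56), AT1G52820 (-2.36), AT5G37450 (-2.32) and UGT72E1 (-1.59). Nuclear photosynthesis genes were lower in 8 of 20 (camera adjusted p = 6.73e-05; adjusted p = 0.244 with an estimated correlation), and plastid-encoded genes in 4 of 69, 4 also when adjusted over the list alone (camera adjusted p = 0.00534; adjusted p = 0.517 with an estimated correlation, 0.22 without Col-0 control replicate 3 and 0.084 without oxMYB72 control replicate 1). There 1686 probe sets were called, 871 higher and 815 lower, with a share higher of 51.7% that became 65.1% after median centring and 46.2% with only the arrays compared. The lower ones numbered 443 without Col-0 control replicate 2 (share higher 60.6%), and 513 and 511 without oxMYB72 control replicates 1 and 2. With WCS417 it was higher in AT4G33720 (5.43), AT4G33710 (2.14), AT1G12130 (1.93), AT5G61290 (1.81) and AT4G22610 (1.62) and lower in AT3G24510 (-4.93), AT4G37290 (-4.22), AT1G26380 (-4.08), AT4G12500 (-3.82) and AT1G26410 (-3.62), with 969 probe sets called, 460 higher and 509 lower. Without oxMYB72 WCS417 replicate 3, AT4G33710 was higher by 2.81, and with only the arrays compared 290 probe sets were higher.

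The WCS417 effect itself was smaller in oxMYB72 than in Col-0 for AT3G24510 (-5.03 ± 0.25), AT1G26380 (-4.55 ± 0.78), AT4G37290 (-4.38), AT1G26410 (-4.19) and AT1G26390 (-4.19), and larger for AT4G33710 (1.99 ± 0.45), EXPB2 (1.69), AT5G10040 (1.53), AT4G10270 (1.44) and AT5G37450 (1.43). This difference called 398 probe sets, 319 lower and 79 higher. The higher ones numbered 34 without oxMYB72 control replicate 2, 44 without Col-0 control replicate 2, 51 without Col-0 WCS417 replicate 2, and 52 without Col-0 control replicate 1, Col-0 WCS417 replicate 3 or oxMYB72 control replicate 1. The 319 lower ones had a median WCS417 effect of 0.82 in myb72-2 and -0.28 in oxMYB72, so lower is not always a smaller rise. Of these, 181 were higher in untreated oxMYB72 than in myb72-2 (median of the 319 0.6), against 804 of all 22746. In colonized roots 169 were lower (median -0.56), against 605 of all 22746. The 319 were chosen from these same oxMYB72 arrays, which favours high untreated and low colonized values there. The 2 counts and the median effect of -0.28 therefore follow in part from the choice. The coumarin list had a lower effect, with 3 of 7 members called, 3 also when adjusted over the list alone (camera adjusted p = 2.21e-06, adjusted p = 0.00684 with an estimated correlation). As given above, coumarin genes stood higher as a list in untreated oxMYB72 than in myb72-2. A lower effect therefore need not mean a lower level in colonized oxMYB72. The list call for colonized oxMYB72 against myb72-2, given above, depended on single arrays. Immune signalling genes had a lower effect in 3 of 20 (camera adjusted p = 0.000841, adjusted p = 0.197 with an estimated correlation). These were STZ at -1.34, PUB24 at -0.85 and BIK1 at -0.67, where a lower effect can be a smaller rise or a fall. The nuclear photosynthesis and plastid-encoded lists, both lower with WCS417 in Col-0, had a less negative effect in oxMYB72. For nuclear photosynthesis genes 2 of 20 were called, 2 also when adjusted over the list alone (camera adjusted p = 0.00866; adjusted p = 0.472 with an estimated correlation), a call that ended without Col-0 control replicate 3 (0.074), oxMYB72 control replicate 3 (0.14) or oxMYB72 WCS417 replicate 1 (0.052). Of the plastid-encoded genes, limma called 0 of 69, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.00197; adjusted p = 0.491 with an estimated correlation and 0.14 without Col-0 control replicate 3). The call of AT4G33710 ended without Col-0 control replicates 1 (1.94) or 2 (2), Col-0 WCS417 replicate 2 (1.83), oxMYB72 control replicate 2 (1.91) or oxMYB72 WCS417 replicates 1 (1.65) or 2 (1.67), and its difference was 2.66 without replicate 3 of that group. That of AT5G10040 ended without Col-0 control replicate 3 (1.44), Col-0 WCS417 replicate 2 (1.37), oxMYB72 control replicates 2 (1.47) or 3 (1.45) or oxMYB72 WCS417 replicate 1 (1.36). In 7 of 100 regroupings of the arrays, which also respond to constant differences between genotypes, at least 398 probe sets were called, against 1 of 100 with genotype effects removed.

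Against myb72-2 the difference of the WCS417 effect called 633, 422 lower and 211 higher, with a share higher of 33.3% that became 20.3% after median centring. The higher ones numbered 113 without oxMYB72 control replicate 2, 126 without oxMYB72 WCS417 replicate 2, 127 and 134 without myb72-2 control replicates 3 and 1, and 124 with only the arrays compared. AT3G24510 (-4.82), AT4G37290 (-4.49), AT1G26410 (-4.25), AT1G26420 (-4.21) and AT5G38910 (-4.15) led the lower ones and AT5G14650 (2.23), EXPB2 (2.08), AT4G33710 (1.9), BGLU42 (1.69 ± 0.17) and BHLH101 (1.62 ± 0.24) the higher ones. The iron deficiency signalling list had a larger effect, with 2 of 10 called, 2 also when adjusted over the list alone (camera adjusted p = 0.00402; adjusted p = 0.133 with an estimated correlation), and nuclear photosynthesis genes a less negative one, with 2 of 20 called and 7 when adjusted over the list alone (camera adjusted p = 0.000705; adjusted p = 0.2 with an estimated correlation). The coumarin list was called here as well, in a direction not given here, but not without myb72-2 WCS417 replicate 3 (camera adjusted p = 0.054). AT4G33710 lost its call without myb72-2 control replicates 1 (1.88) or 2 (1.87), oxMYB72 control replicate 2 (1.82) or oxMYB72 WCS417 replicates 1 (1.56) or 2 (1.58), and its difference was 2.57 without replicate 3 of that group. In 2 of 100 regroupings of the arrays at least 633 probe sets were called, and in 1 of 100 with genotype effects removed. Of 319 probe sets that rose at least 2-fold with WCS417 in myb72-2, which shares no array with the comparison of oxMYB72 and Col-0, 136 had a smaller effect in oxMYB72 than in Col-0 and 6 a larger one.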

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

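The regroupings of arrays within each treatment were planned before their results were seen. The tests on the 319 induced probe sets and parts of them, the regroupings with genotype effects removed and the permutation of residuals were chosen after the results they bear on had been seen.

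The response to WCS417 differed between genotypes in all 3 tests of the difference, with 4, 398 and 633 probe sets called for myb72-2 minus Col-0, oxMYB72 minus Col-0 and oxMYB72 minus myb72-2. For myb72-2 minus Col-0 the named genes were CYP71B5 (-2.03), AT5G55620 (-1.8) and BGLU42 (-1.52). For oxMYB72 minus Col-0 they were AT4G33710 (1.99), EXPB2 (1.69), AT5G10040 (1.53), AT4G10270 (1.44), AT5G37450 (1.43), AT3G24510 (-5.03), AT1G26380 (-4.55), AT4G37290 (-4.38), AT1G26410 (-4.19) and AT1G26390 (-4.19). For oxMYB72 minus myb72-2 they were AT5G14650 (2.23), EXPB2 (2.08), AT4G33710 (1.9), BGLU42 (1.69), BHLH101 (1.62), AT3G24510 (-4.82), AT4G37290 (-4.49), AT1G26410 (-4.25), AT1G26420 (-4.21) and AT5G38910 (-4.15). AT4G33710 lost its call in 2 of these tests without single arrays, under the variance trend with robust moderation and with only the arrays compared.

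The planned test reassigned genotype among the arrays of each treatment in 100 regroupings, the real one included. At least as many probe sets were called in 17 of 100 for myb72-2 minus Col-0 (highest other 76 against 4), in 7 for oxMYB72 minus Col-0 (1301 against 398) and in 2 for oxMYB72 minus myb72-2 (767 against 633). By construction this test also responds to constant differences between genotypes, which an unequal exchange in the 2 treatments turns into an apparent difference of responses, so its shares are not those of chance for these differences. With the genotype effects removed first, the same regroupings gave 2, 1 and 1 of 100, with highest others of 5, 2 and 40. Permuting residuals after removal of genotype and treatment effects also gave 2, 1 and 1 of 100, with highest others of 4, 12 and 107. Both tests were chosen after the planned one had come out, which weakens them. For oxMYB72 minus Col-0 and oxMYB72 minus myb72-2 none of the others reached the real count, which argues against chance. For myb72-2 minus Col-0 another regrouping called 5 and another permutation 4, against the real 4. A share of 2 of 100 is under 0.05 and argues against chance there too, more weakly and without excluding it. The count takes no account of strength. The 4 probe sets had adjusted p-values in limma from 8e-07 to 0.0015 and kept their calls without each array in turn.

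The smaller induction in oxMYB72 covered 136 of the 319 probe sets that rose at least 2-fold in myb72-2. A response weaker by 1 factor for all genes needs rises and falls to shrink alike. The ratio of median effects, oxMYB72 over Col-0, was 0.48 for rises and 0.84 for falls. The difference of 0.36 (0.33 to 0.4 with each array left out) argues against 1 such factor as the whole cause. Lower bacterial numbers need not shrink all effects by 1 factor, so the ratios cannot decide on them. If the genes stood at their colonized level in untreated oxMYB72 already, colonized levels would match. Over the 319, chosen in myb72-2 alone, the median difference of colonized oxMYB72 from Col-0 was -0.56 (-0.64 to -0.55 with each array left out). This argues against a raised untreated level as the whole cause. Of these 319, 164 were called lower in colonized oxMYB72 than in Col-0, 65 higher in untreated oxMYB72, and 30 both. A raised untreated level stays open for a part of them. Over the 136 the median was -1.21, but these were chosen from the same arrays: 82 were called lower in colonized oxMYB72 and not higher in untreated oxMYB72, 30 were called both, and for 23 called higher untreated and not lower colonized no test was made and it stays open. A change tied to the transgene stays open as a hypothesis, with only 1 transgenic line and no measure of colonization used here, so that an effect of the insertion site was not tested.

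For each comparison of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the only 1 with as many calls for the WCS417 effect in Col-0 (3491), myb72-2 (4870) and oxMYB72 (4391), for myb72-2 against Col-0 without bacteria (9), for oxMYB72 against myb72-2 without bacteria (1548) and for oxMYB72 against Col-0 without (1686) and with WCS417 (969), with a highest other of 0 in each. For oxMYB72 against myb72-2 with WCS417 the highest other was 669 against 1256. For myb72-2 against Col-0 with WCS417, 2 of 10 splits gave at least 29, and another split called 260. That split set Col-0 replicates 1 and 3 and myb72-2 replicate 3 against the other 3 colonized arrays, so the colonized arrays hold a structure that genotype does not describe. It follows the interquartile range of the arrays. This was 4.01 in Col-0 replicate 2 and 3.996 and 3.913 in myb72-2 replicates 1 and 2, against 4.071 to 4.162 on the other side. The split with 669 set the same 2 myb72-2 arrays and oxMYB72 replicate 1 (3.969) against arrays at 4.095 to 4.162. The cause of the narrower range was not tested. For the average over genotypes 1 of 100 regroupings, the real one included, gave as many as 8549, with a highest other of 13, which argues against chance. Regrouping cannot separate WCS417 from what went with it, such as the larger 3′ minus 5′ differences of actin and GAPDH.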

How the results depend on the processing

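Alternatives were planned before the data were examined, except leaving out arrays for the correlations between genotypes and the alternatives of single genes, which were chosen after seeing the data. The values gave no sign that replicate numbers pair the arrays throughout. Correlations of deviations between same-numbered arrays ran from -0.3 to 0.26, and 7 of 18 arrays correlated best with their own number. Between Col-0 and myb72-2 with WCS417 they were -0.08, 0.26 and 0.19 for replicates 1, 2 and 3, so a partial pairing is not excluded. With a replicate block the counts were 3426, 4829, 4355 and 8547 for the WCS417 effects in Col-0, myb72-2, oxMYB72 and their average, and 10 and 31 for myb72-2 against Col-0 without and with WCS417. No named gene changed direction in any alternative run. No called list changed direction in an alternative that gave a direction and still called it. A list that turned without a call was not looked for. With only the arrays compared, the counts were 1 and 6 for myb72-2 against Col-0 without and with WCS417 and 588 for oxMYB72 against myb72-2 with WCS417. Counts also fell for the WCS417 effect in myb72-2 (3479) and oxMYB72 (3789), oxMYB72 against Col-0 with WCS417 (650) and the difference oxMYB72 minus myb72-2 (479), and those for oxMYB72 against myb72-2 (1956) and Col-0 (2246) without bacteria, the WCS417 effect in Col-0 (3762) and the difference oxMYB72 minus Col-0 (418) rose, and the cause was not tested. A variance trend with robust moderation gave 45 for myb72-2 against Col-0 with WCS417, where the cause was not tested either. Removing the dimmest probe sets left 2 for the difference of the WCS417 effect between myb72-2 and Col-0, as CYP71B5 and AT5G55620 were among those removed, and gave correlations of 0.921, 0.702 and 0.68 for Col-0 with myb72-2, Col-0 with oxMYB72 and myb72-2 with oxMYB72. Over probe sets called in either genotype they were 0.947, 0.714 and 0.692. Of 325 list tests 60 were called, against 11 with an estimated correlation and 85 with fry's directional test, 45 of them among the 60. Its mixed test called 180, and neither test by fry compares a list with other genes.

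With each array left out, counts ran from 2290 to 3005 for the WCS417 effect in Col-0, from 3739 to 5419 in myb72-2, from 2950 to 4337 in oxMYB72 and from 7841 to 8991 for the average. They ran from 1 to 8 and from 11 to 121 for myb72-2 against Col-0 without and with WCS417, from 1005 to 1219 and from 1009 to 1665 for oxMYB72 against myb72-2, and from 1125 to 1474 and from 733 to 859 for oxMYB72 against Col-0. For the differences of effects they ran from 4 to 6, from 278 to 398 and from 443 to 672. The correlations ran from 0.847 to 0.888, from 0.649 to 0.683 and from 0.603 to 0.661, and called lists from 50 to 62. Dim probe sets limit small changes, since RMA compresses differences near the background.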

Other observations

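The tests on the chromosome 3 run were chosen after the run had been seen. Genes of histones and mitosis, a list added later, were higher with WCS417 in 10 of 16 members in oxMYB72 (camera adjusted p = 0.000299; adjusted p = 0.223 with an estimated correlation), with BUBR1 at 0.72 ± 0.12, HTB2 at 0.68 and TOPII at 0.68. The list was higher in the other genotypes too, with 4 of 16 called in Col-0 (camera adjusted p = 0.026; adjusted p = 0.472 with an estimated correlation, and 0.082 and 0.058 without Col-0 WCS417 replicates 1 and 3) and 7 of 16 in myb72-2 (camera adjusted p = 0.0251; adjusted p = 0.576 with an estimated correlation and 0.15 without myb72-2 WCS417 replicate 3). In oxMYB72 endoglucanases were higher in 5 of 15 (camera adjusted p = 0.0223; adjusted p = 0.18 with an estimated correlation), with GH9C2 at 1.11, GH9B8 at 0.88 and GH9B13 at 0.73.

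A run of 22 neighbouring genes on chromosome 3, among those left after removal of the 30% dimmest, from AT3G01690 to AT3G02120, was lower in untreated myb72-2 than in Col-0 by a median of -0.53 (SD over genes 0.13). In the colonized arrays, which were not used to find it, 22 of 22 were lower, by a median of -0.52 (SD 0.16), and oxMYB72 was lower than Col-0 by -0.57 and -0.48 without and with WCS417. None of 1000 random gene orders (0) gave a run of as large a summed deficit (5.02 against at most 1.77). If MYB72 raised these genes, the transgene should bring them back, but it made up 11% of the deficit in colonized roots (3.8% to 15.2% with each array left out). Sequence variants under the probes should scatter the shifts, but their SD was 1.04 times that outside the run (0.86 to 1.25 with each array left out). A candidate explanation is a difference in the segment itself between the Col-0 stock and the background of both lines, which was not tested.

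The probe set with no gene in the annotation used, chosen after its values were seen, stood at 12.44 ± 0.2 in untreated oxMYB72, 3.64 ± 0.35 in myb72-2 and 3.53 ± 0.2 in Col-0 (SD, n = 3), and rose with WCS417 by 3.35 in Col-0 and by 0.1, not called, in myb72-2. AT4G33666 and AT4G33720, near each other on chromosome 4, were higher in untreated oxMYB72 than in myb72-2, AT4G33666 at 10.15 ± 0.12 against 7.91 ± 0.27. AT4G33710 beside them differed by 0.25, not called, in untreated roots and by 2.15, called, with WCS417.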
